A study of Homo sapiens with 84 samples.

How the data were processed

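The data are 84 gene expression libraries of 2 established non-small cell lung cancer lines, NCI-H1373 and NCI-H647. Cells were exposed to RBN-2397 (10, 30 or 300 nM), to RBN012337 (3, 10 or 100 nM) or to the vehicle DMSO for 6 or 24 h. Per the labels both compounds inhibit PARP7, the mono-ADP-ribosyltransferase encoded by TIPARP, and each set of doses was chosen near the concentrations that inhibit 25%, 50% and 90%. The sample labels write the first compound as RBN012397 and the design text as RBN-2397, with the same doses, and the second spelling is used here. Line, time, compound and dose give 28 groups of 3 libraries, and every group carries replicates 1 to 3 in its titles. The labels speak of experiments done in triplicate and give no culture, plate or day for a replicate, so p-values measure the spread between these libraries, which may be partly technical.

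Per the labels' protocols, total RNA was made into 3' digital gene expression libraries, which read the ends of transcripts, with paired-end reads. The authors deposited one table of estimated counts per gene, neither normalized nor pooled. Per the submitters' processing notes the counts come from Salmon and the hg38 build. The annotation, the handling of molecular identifiers and the handling of strand are not given in the sources used here. Reads of near-identical gene copies, of overlapping genes and of antisense pairs can therefore be shared between them, and such genes are given as uncertain. The table holds 57964 Ensembl genes, and 49.4% of its nonzero values were not whole, as an estimating counter gives. Columns were matched to samples by title. Names, types and positions were taken from GENCODE 29 on GRCh38, by identifier without version, for 57845 genes. Intervals and floors from counts cover counting error only, since duplicates from amplification cannot be told from molecules here.

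The estimated counts were rounded to whole numbers. Total counts ran from 630855 to 5994444 per library in NCI-H1373 and from 1769332 to 6938648 in NCI-H647, with 13600 to 22469 genes detected. In NCI-H1373 the 7 libraries of replicate 3 at 6 h and the 14 of replicates 2 and 3 at 24 h hold 630855 to 2011578 counts, and the other 21 hold 2481960 to 5994444. Both depths occur once or more in each group of that line, so depth is not confounded with treatment. Replicates of a group were compared pairwise, and all 84 pairs differed by more than sampling noise, with a chi-square of 3.90 to 44.1 per degree of freedom over genes of at least 50 summed counts. A check of line identity by expressed genes found 84 of 84 libraries with their own line.

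Each line was fitted alone with the 42 libraries of its 14 groups in 1 model, so that all groups share an estimate of the spread. Genes were kept by filterByExpr of edgeR 4.0.16 (12832 in NCI-H1373 and 14789 in NCI-H647), scaled by TMM and tested with the edgeR quasi-likelihood F test with robust dispersions. P-values were adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05, and a gene past it is called higher or lower. Differences between the lines used all 84 libraries and 16177 genes. By chance 642 (NCI-H1373), 739 (NCI-H647) and 809 (between lines) genes would have an unadjusted p under 0.05. The contrasts were 24 treatments against DMSO of the same line and time, 4 differences between compounds at 10 nM, 4 at the top dose (300 nM against 100 nM), 2 differences of the response to RBN-2397 at 300 nM between times and 2 between lines. The 4 contrasts of RBN-2397 at 300 nM with DMSO are the main comparisons. Errors beside a log2 fold change are standard errors from this fit with 3 libraries per group, and errors beside a mean are standard deviations.

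The design, the lists and the rule for named genes were set before the data were examined. The rule takes, in each main comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean count of at least 5 in the higher group and no overlap of the 3 treated with the 3 DMSO libraries. In 3 against 3 libraries chance alone separates a gene without overlap in 10% of cases. It takes 3 genes each way in other treatments, 5 in differences, up to 4 members of a described list by smallest adjusted p, and TIPARP everywhere. Some genes that met the rule are not reported here. Where the reference group holds no count, a fold is a lower bound against 3 counts over the group. With 1 to 3 counts the ratio is given with an exact 95% interval for counting error.

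The 26 lists cover interferon-stimulated genes, interferons and T-cell chemokines, NF-kB targets, MHC class I presentation, nucleic acid sensing, aryl hydrocarbon receptor targets, the PARP family, immune checkpoint ligands, DNA replication, mitosis, p53 targets, the unfolded protein and integrated stress response, cholesterol synthesis, glycolysis and hypoxia, NRF2 targets, ERK output and immediate early genes, apoptosis regulators, epithelial adhesion and keratins, mesenchymal genes, squamous differentiation, lung lineage, TGF-beta and YAP targets, leukocyte markers, fibroblast and endothelial markers, mitochondrially encoded transcripts and cytosolic ribosomal proteins. A list was tested where at least 5 members passed the filter, which left 23 lists in each line and 25 over both. The test was camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a contrast, and it was repeated with a correlation estimated from the data and with fry. A list score is the mean log2 CPM of the tested members in a library, and the 95% intervals of score differences come from a linear model over the 14 groups (42 libraries) of a line. The score differences between doses and compounds were repeated with the replicate number within time as a block and without each library of the 2 groups. The lists share members (TIPARP, PARP9 and others), so their tests are not independent.

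The replicate numbers pair libraries in part. Deviations from the group means were correlated between libraries of the same line and time, and 82 of 84 libraries correlated best with libraries of their own number. The median correlation of same-numbered libraries was 0.48 and 0.38 at 6 and 24 h in NCI-H1373, and 0.29 and 0.29 in NCI-H647. A contrast counts as paired where all 3 same-numbered pairs of its groups exceeded 0.1. This held in NCI-H1373 at 6 h for each treatment except RBN012337 at 10 nM, in NCI-H1373 at 24 h for RBN-2397 at 30 and 300 nM and RBN012337 at 3 and 100 nM, in NCI-H647 at 6 h for RBN012337 at 100 nM, and for 6 of 8 compound differences.

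The alternatives were RLE scaling, the DESeq2 1.42.0 Wald test, no filter, a filter of at least 20 counts in 3 libraries, the replicate number as a block, a fit of the contrast's groups alone, RBN012337 at 100 nM in place of RBN-2397 in the time and line differences, and leaving out each library in turn. Chosen after seeing the data were the repeats of score differences, a covariate for the 2 depth sets of NCI-H1373, and 1 depth set alone. So was leaving out 3 DMSO libraries that stand apart by total count, genes detected or the share of counts in 10 genes. They are replicate 3 of 24 h in each line and replicate 2 of 6 h in NCI-H647. No scaling alternative moved the median of all genes by over 0.1 on the log2 scale. Similarity of responses was measured across genes, which are not independent replicates, beside 20 simulated sets of unchanged groups where comparisons share DMSO libraries. Splits of the libraries were counted in full for 3 against 3 (10 splits). For each time and line difference 40 regroupings were drawn, for the lines after smaller numbers.

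The fit was tested on simulated data in R 4.3.3 with counts drawn from the real means and library sizes and 200 genes changed. For RBN-2397 at 300 nM at 24 h in NCI-H1373 (12370 genes), it recovered 14.3% of 2-fold, 58.3% of 3-fold and 70.8% of 4-fold changes. In NCI-H647 (14531 genes) it recovered 10.0% of 2-fold, 62.5% of 3-fold and 82.0% of 4-fold changes. Smaller changes were mostly below what 3 libraries of this depth and spread can show.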

Results

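Gene expression was measured with 3' digital gene expression libraries in NCI-H1373 and NCI-H647, established lung cancer lines. Each line was exposed for 6 or 24 h to DMSO, to RBN-2397 at 10, 30 or 300 nM, or to RBN012337 at 3, 10 or 100 nM. Every group held 3 libraries, which gives 28 groups and 84 libraries. Total counts ran from 630855 to 6938648 per library. Both compounds inhibit PARP7, and the comparisons ask which genes respond to this, at which dose and time, and whether compounds, times and lines differ. The plot of genes called by treatment shows the 24 comparisons with DMSO.

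**Figure D1:**
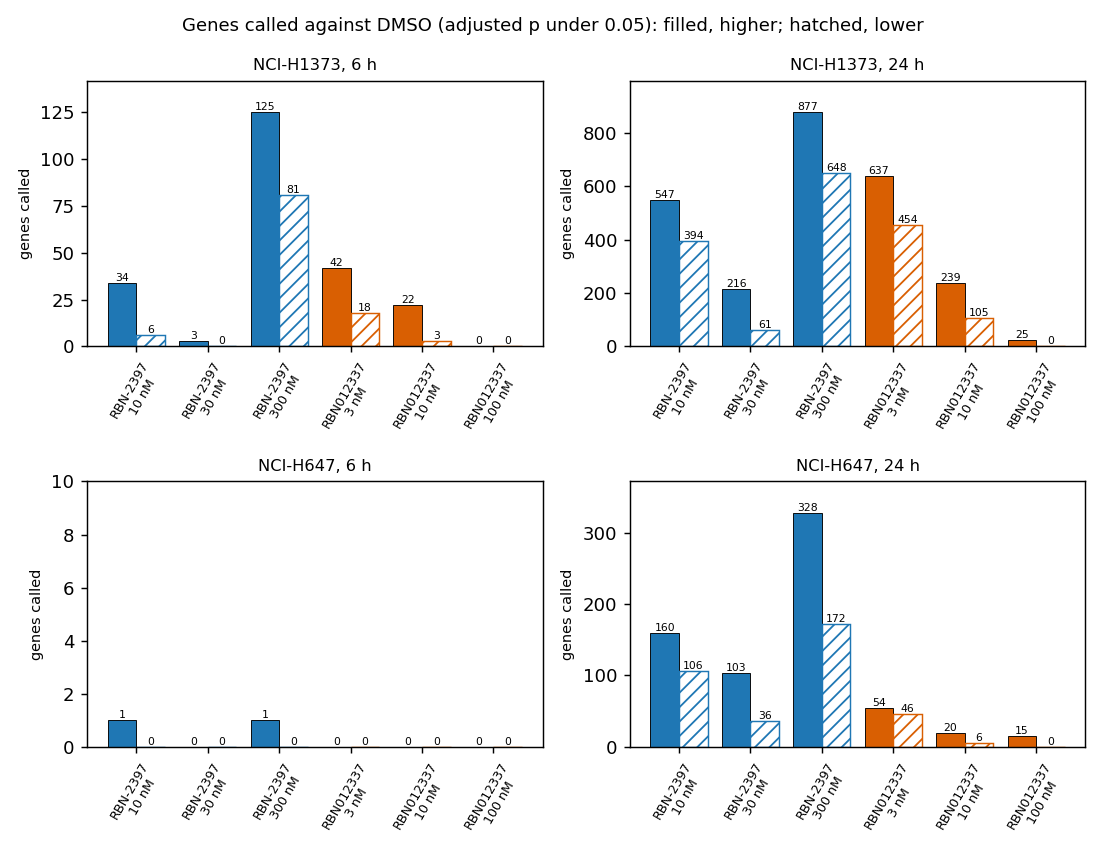
Number of genes called (y axis, adjusted p under 0.05, edgeR) higher (filled bars) or lower (hatched bars) than DMSO for each compound and dose (x axis), by line and time, with 3 libraries per group. The y axes differ between panels, from 1 gene in NCI-H647 at 6 h to 877 higher and 648 lower in NCI-H1373 at 24 h with RBN-2397 at 300 nM.

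The early response to RBN-2397 was measured after 6 h at 300 nM in NCI-H1373. CYP1B1 (ENSG00000138061.11, chromosome 2, 38066973 to 38109902 on GRCh38), a cytochrome P450 induced by the aryl hydrocarbon receptor, rose by 3.91 ± 0.75 on the log2 scale (n = 3 per group, adjusted p = 0.0115). It was the 1 of 10 tested aryl hydrocarbon receptor targets past the threshold (6 adjusted over the list alone). Values were 1.93 ± 0.57 for AHRR, the repressor of the receptor (adjusted p = 0.0719), and 4.71 ± 1.37 for the monooxygenase gene CYP1A1 (adjusted p = 0.0721). The list was called higher (median 1.06, adjusted p = 0.0044), and this call was lost with an estimated correlation (adjusted p = 0.194). Replicate 1 of the treatment stood apart within this list, with CYP1B1 at 11.2 CPM against at most 18.3 CPM in DMSO and at least 112 CPM in the other 17 treated libraries.

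Of 12 TGF-beta and YAP targets in the same comparison 2 rose (3 adjusted over the list alone), among them PMEPA1 by 1.18 ± 0.27. The list median was 0.54 (adjusted p = 0.0044, and adjusted p = 0.0787 with an estimated correlation). Of 15 NF-kB targets 2 rose (4 adjusted over the list alone), the cytokine gene LIF by 3.08 ± 0.72 and the chemokine gene CXCL2 by 3.03 ± 0.76. This list was called higher at a median of 0.45 (adjusted p = 0.00857, and adjusted p = 0.194 with an estimated correlation). Of 25 mitosis genes 1 fell (8 adjusted over the list alone), the spindle gene NUSAP1, at −1.13 ± 0.28, and the list was called lower (median −0.40, adjusted p = 6.6e-05, and adjusted p = 0.194 with an estimated correlation). The lists of 13 mitochondrially encoded transcripts and 34 cytosolic ribosomal proteins, read as signs of RNA quality, were called lower with medians of −0.27 and −0.19 and no member past the threshold (adjusted p = 0.0233 for each). With an estimated correlation their adjusted p = 0.652 and 0.849.

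Of 21 ERK output and immediate early genes 1 rose and 2 fell (8 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.0628). The stress gene IER3 rose by 1.69 ± 0.32, while the immediate early transcription factor genes EGR1 and FOS stood at −2.58 ± 0.59 and −2.90 ± 0.70. Of 51 interferon-stimulated genes 0 passed the threshold in edgeR (median 0.13, list adjusted p = 0.702). DNA replication, PARP family, MHC class I presentation, nucleic acid sensing, immune checkpoint ligands, p53 targets, unfolded protein and integrated stress response, cholesterol synthesis, glycolysis and hypoxia, NRF2 targets, apoptosis regulators, epithelial adhesion and keratins, mesenchymal genes, squamous differentiation and lung lineage were not called either (adjusted p = 0.299 to 0.985).

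Across all genes 206 of 12832 were called, 125 higher and 81 lower. Among the 10 largest rises that met the naming rule were RUNX2, a transcription factor of bone formation (3.32 ± 0.78), and INHBA, an activin subunit (4.14 ± 0.93). THBD, the thrombin receptor thrombomodulin, held 76 counts against 2 in DMSO (ratio 29.8 after scaling to depth, 95% counting interval 7.96 to 250). Among the 10 largest falls were EGR1, the corepressor gene TLE4 (−4.48 ± 1.20) and the sestrin gene SESN3 (−3.62 ± 0.96). The non-coding AL731571.1, with 0 counts in treated libraries and 84 in DMSO, was at least 35.7-fold lower, and the pseudogene FAM86EP (4.03 ± 0.90) is uncertain because its reads can be shared with its family. Without 1 library the count was 0 (treated replicate 2 or DMSO replicate 2 left out), 68 and 104 (treated replicates 1 and 3), or 358 and 349 (DMSO replicates 1 and 3). With the replicate number as a block it was 830.

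The other doses at 6 h in NCI-H1373 show how this early response varies with compound and dose. CYP1B1 rose by 4.23 ± 0.76 and 4.25 ± 0.76 with RBN-2397 at 10 and 30 nM, and by 3.74 ± 0.75 and 5.38 ± 0.80 with RBN012337 at 3 and 10 nM. With RBN012337 at 100 nM the value was 3.91 ± 0.76 (adjusted p = 0.161). The list of aryl hydrocarbon receptor targets was called higher at each of these doses, and the call held with an estimated correlation for RBN-2397 at 30 nM (adjusted p = 0.0075) and RBN012337 at 10 and 100 nM (adjusted p = 0.00359 and 0.0213). TGF-beta and YAP targets also held at 30 nM of RBN-2397 (median 0.42, adjusted p = 0.0463 with an estimated correlation) and 10 nM of RBN012337 (0.37, adjusted p = 0.0151), as did mitosis, which was lower at 30 nM (−0.30, adjusted p = 0.0463). The receptor call was lost for RBN-2397 at 10 nM (adjusted p = 0.0691 with an estimated correlation) and for RBN012337 at 3 nM (adjusted p = 0.138 with an estimated correlation). The interferon list was called higher at the same 5 doses with medians of 0.13 to 0.30, and this was lost at each (adjusted p = 0.685 to 0.952 with an estimated correlation). RSAD2, an antiviral gene induced by interferon, rose by 2.68 ± 0.48 with RBN012337 at 10 nM. The 3 genes called with RBN-2397 at 30 nM were CYP1B1, the AP-1 subunit gene FOSL2 (1.78 ± 0.34) and IER3 (1.71 ± 0.32). TIPARP (ENSG00000163659.12, chromosome 3, 156673235 to 156706770), which encodes the target of both compounds, rose by 1.59 ± 0.33 with RBN012337 at 10 nM (adjusted p = 0.0216) and had values of 0.81 to 1.33 at the other 5 doses (adjusted p = 0.0848 to 1). RUNX2 rose by 3.37 ± 0.77 with RBN-2397 at 10 nM and by 3.20 ± 0.77 with RBN012337 at 3 nM.

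Counts for these doses were 40 (34 higher, 6 lower) and 3 (3 higher) with RBN-2397 at 10 and 30 nM. With RBN012337 they were 60 (42 higher, 18 lower) at 3 nM, 25 (22 higher, 3 lower) at 10 nM and 0 at 100 nM by edgeR (329 with an unadjusted p under 0.05, and 2 by DESeq2). Without 1 library the counts ran from 0 (replicate 2) to 191 (DMSO replicate 3) with RBN-2397 at 10 nM, from 0 (replicate 1) to 163 (replicate 2) at 30 nM. They ran from 0 (DMSO replicate 2) to 257 (DMSO replicate 3) with RBN012337 at 3 nM, from 2 (DMSO replicate 2) to 20 (DMSO replicate 3) at 10 nM, and from 0 to 1 (replicate 1) at 100 nM. With the replicate number as a block they were 505 and 16 with RBN-2397 at 10 and 30 nM and 547 with RBN012337 at 3 nM.

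**Figure D2:**
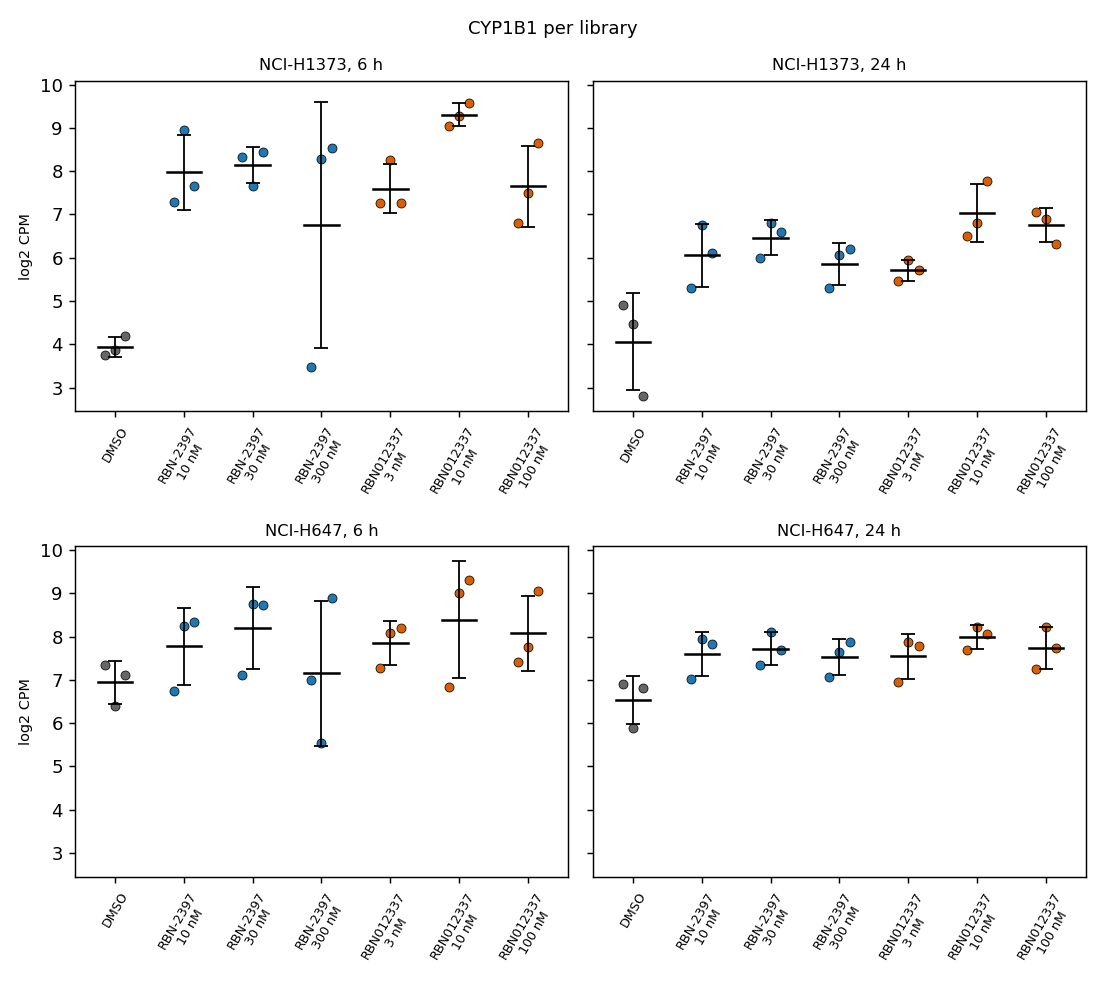
CYP1B1 in log2 CPM (y axis) per library for DMSO and each compound and dose (x axis), by line and time; points are the 3 libraries, lines the mean and bars the SD. At 6 h in NCI-H1373 the treated libraries lie above the 3 DMSO libraries except replicate 1 of RBN-2397 at 300 nM, at 11.2 CPM.

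The later response was measured after 24 h with RBN-2397 at 300 nM in NCI-H1373. Of 51 interferon-stimulated genes 41 rose and 0 fell (48 adjusted over the list alone), and all 51 had positive log2 changes (n = 3 per group). OASL (ENSG00000135114.12, chromosome 12, 121019111 to 121039242), an antiviral protein related to the oligoadenylate synthetases, rose by 5.21 ± 0.78 (adjusted p = 0.000226). IFIT2, which restrains viral translation, rose by 4.0 ± 0.65, EIF2AK2, the kinase activated by double-stranded RNA, by 1.64 ± 0.29 and UBE2L6, the conjugating enzyme of ISG15, by 2.12 ± 0.38. The list median was 2.12 (adjusted p = 8.42e-39), and its adjusted p = 0.0639 with an estimated correlation. Of 14 PARP family genes 6 rose (7 adjusted over the list alone), PARP9 by 2.27 ± 0.45, PARP10 by 3.00 ± 0.65 and PARP14 by 1.43 ± 0.34 (list adjusted p = 0.000631, and adjusted p = 0.0765 with an estimated correlation). Of 14 nucleic acid sensing genes 5 rose (6 adjusted over the list alone), among them the DNA sensor genes AIM2 (2.70 ± 0.57) and IFI16 (1.57 ± 0.37) and the nucleotide hydrolase gene SAMHD1 (1.56 ± 0.33). As a list they were called higher (adjusted p = 0.000631, and adjusted p = 0.0639 with an estimated correlation). Of 16 MHC class I presentation genes 2 rose (3 adjusted over the list alone), the immunoproteasome subunit genes PSMB8 (1.50 ± 0.33) and PSMB9 (1.06 ± 0.29). This list was called higher (adjusted p = 0.00422, and adjusted p = 0.317 with an estimated correlation). Of 10 aryl hydrocarbon receptor targets 3 rose (5 adjusted over the list alone), the aldehyde dehydrogenase genes ALDH1A3 (3.99 ± 0.74) and ALDH3A1 (3.74 ± 0.86) and the growth factor gene EREG (2.52 ± 0.71). As a list they were called higher (adjusted p = 0.00302, and adjusted p = 0.169 with an estimated correlation). CYP1B1 stood at 1.43 ± 0.72 (adjusted p = 0.207) and TIPARP at 0.81 ± 0.34 (adjusted p = 0.112).

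**Figure D3:**
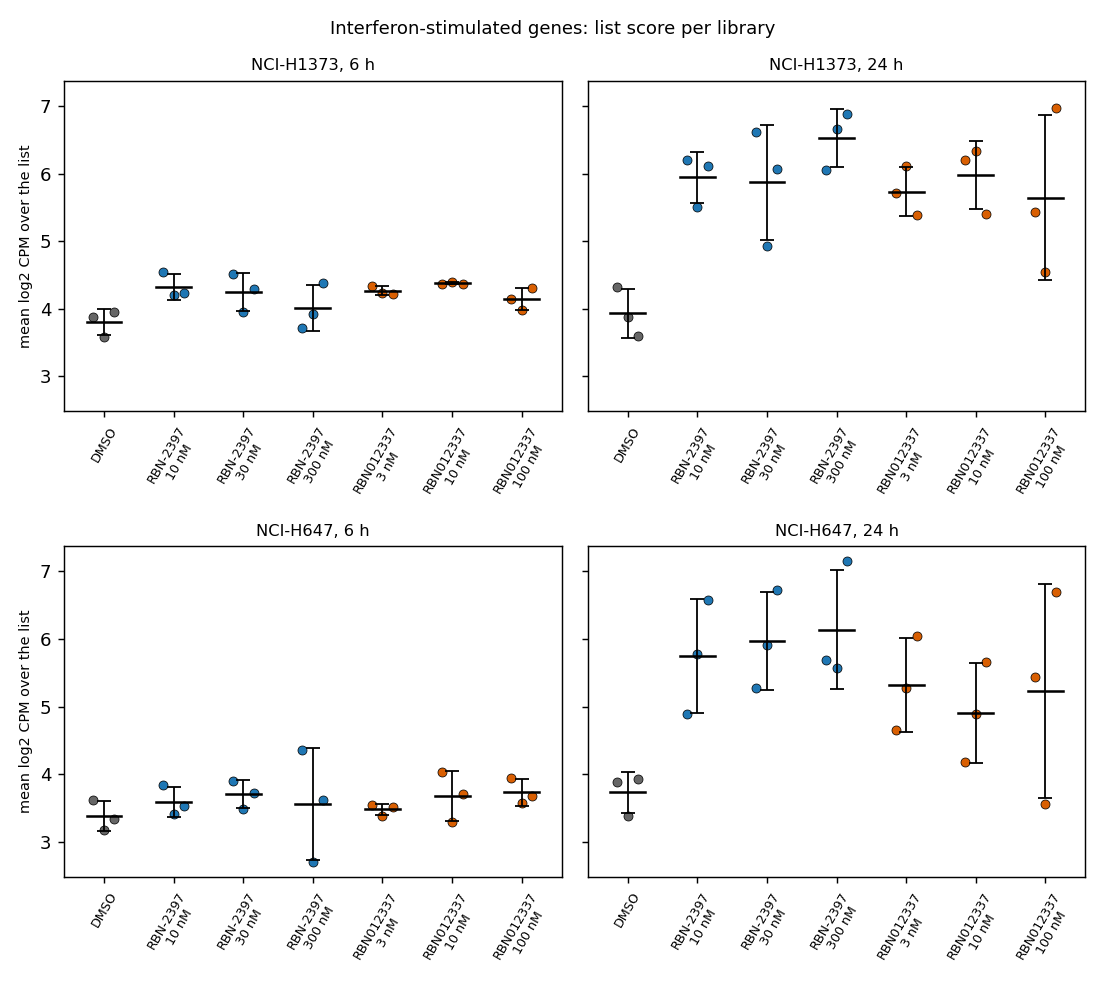
Mean log2 CPM over 51 interferon-stimulated genes (y axis) per library for DMSO and each compound and dose (x axis), by line and time; points are the 3 libraries, lines the mean and bars the SD. At 24 h in NCI-H1373 the 18 treated libraries score at least 4.55, above the highest DMSO library at 4.32. In NCI-H647 replicate 2 of RBN012337 at 100 nM, at 3.56, lies within DMSO.

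Genes of growth and lineage also differed at 24 h in NCI-H1373. Of 27 DNA replication genes 8 rose and 0 fell (12 adjusted over the list alone), among them the helicase subunit genes MCM2 (2.08 ± 0.41), MCM6 (1.37 ± 0.29) and MCM7 (1.28 ± 0.30). The list median was 0.71 (adjusted p = 8.64e-07, and adjusted p = 0.253 with an estimated correlation). Of 20 genes of the unfolded protein and integrated stress response 6 fell and 1 rose (9 and 2 adjusted over the list alone), and the list was called lower (adjusted p = 0.0334, and adjusted p = 0.274 with an estimated correlation). The asparagine synthetase gene ASNS stood at −4.82 ± 1.07, the stress transcription factor genes ATF3 and DDIT3 at −4.46 ± 1.01 and −1.64 ± 0.38, and the mTORC1 inhibitor gene DDIT4 rose by 1.79 ± 0.40. The fall of ASNS rests on DMSO replicate 2 (8.27, 139 and 0 CPM in replicates 1, 2 and 3), and without it the call was lost (−1.70, adjusted p = 0.315). The DMSO libraries moved with both lists. Their replication scores ran from 3.88 to 4.96 (SD 0.61), overlapping the 4.81 to 5.28 with RBN-2397 at 300 nM. Their stress response score was 5.41 ± 0.69 against 4.76 ± 0.11 (SD, n = 3). Of 7 lung lineage genes 3 rose (5 adjusted over the list alone), the mucin gene MUC1 by 3.26 ± 0.62 and the transcription factor genes FOXA2 by 1.51 ± 0.38 and NKX2-1 by 1.51 ± 0.39 (list adjusted p = 0.000168, and adjusted p = 0.0639 with an estimated correlation). Of 18 glycolysis and hypoxia genes 5 rose (7 adjusted over the list alone), including the glucose transporter gene SLC2A1 (1.4 ± 0.26), the enolase gene ENO1 (1.04 ± 0.24) and VEGFA (2.80 ± 0.79). This list was called higher (adjusted p = 0.000589, and adjusted p = 0.169 with an estimated correlation). Of 34 ribosomal protein genes 6 rose (7 adjusted over the list alone), with a list median of 0.36 (adjusted p = 0.000108, and adjusted p = 0.427 with an estimated correlation).

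Lists not called at 24 h in NCI-H1373 still held changed members. Of 17 epithelial adhesion and keratin genes 4 rose and 3 fell (8 and 5 adjusted over the list alone), with KRT18 at 1.86 ± 0.29 and KRT19 at 1.54 ± 0.26 (list adjusted p = 0.0542). Of 18 cholesterol synthesis genes 1 rose and 3 fell (list adjusted p = 0.0623). Of 21 ERK output genes 1 rose and 6 fell (list adjusted p = 0.114), with ETV5 at −2.10 ± 0.38 and JUN at −1.64 ± 0.37. Of 12 TGF-beta and YAP targets 2 rose and 5 fell (list adjusted p = 0.496), with the matricellular genes CTGF at −5.17 ± 1.10 and CYR61 at −2.14 ± 0.54. The remaining lists were NF-kB targets (4 higher, 1 lower of 15, adjusted p = 0.0904), mitosis (0 higher, 2 lower of 25, adjusted p = 0.114), p53 targets (2 higher, 3 lower of 18, adjusted p = 0.196), mesenchymal genes (2 higher of 11, adjusted p = 0.275), mitochondrially encoded transcripts (0 of 13, adjusted p = 0.371). They also held immune checkpoint ligands (1 higher of 8, adjusted p = 0.496), apoptosis regulators (2 higher, 1 lower of 15, adjusted p = 0.586), NRF2 targets (3 higher, 1 lower of 13, adjusted p = 0.622) and squamous differentiation (2 higher, 1 lower of 5, adjusted p = 0.724). The cytotoxic ligand gene TNFSF10 (2.86 ± 0.82) and BID, a pro-apoptotic BCL2 relative (2.60 ± 0.45), rose among apoptosis regulators.

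Across all genes 1525 of 12832 were called, 877 higher and 648 lower. The 10 largest rises that met the naming rule included 8 genes without a count in DMSO. The airway mucin gene MUC5B was at least 19.9-fold higher, the non-coding MIR205HG at least 30.9-fold, the oxysterol hydroxylase gene CH25H at least 12.9-fold and the transcription factor gene SOX2 at least 9.82-fold. LGALS9 was at least 6.17-fold higher and CXorf49 held 169 counts against 1 (ratio 142, 95% counting interval 25.2 to 5650); both are uncertain because near-identical copies exist. Among the 10 largest falls were CTGF, ATF3, the GABA synthesis gene GAD1 (−4.30 ± 0.78) and the chaperone gene CLU (−3.88 ± 0.88). Without 1 library the count fell to 470 (DMSO replicate 1), 695 (treated replicate 2) and 876 (treated replicate 3).

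At the other doses for 24 h in NCI-H1373 the interferon-stimulated genes had 28 and 23 of 51 members called higher with RBN-2397 at 10 and 30 nM and 21, 26 and 11 with RBN012337 at 3, 10 and 100 nM. Adjusted over the list alone these counts were 39, 42, 33, 38 and 39, and the medians were 1.56, 1.50, 1.30, 1.56 and 1.50. The list was called at each dose (largest adjusted p = 5.11e-20), and with an estimated correlation it held for RBN012337 at 100 nM (adjusted p = 0.0167) and was lost at the other doses (adjusted p = 0.0567 to 0.179 with an estimated correlation). With RBN012337 at 100 nM the aryl hydrocarbon receptor, PARP family, nucleic acid sensing and squamous differentiation lists also held (adjusted p = 0.0167, 0.0284, 0.0183 and 0.0284 with an estimated correlation). At this dose the chemokine gene CCL5 rose by 5.0 ± 0.60 (adjusted p = 9.13e-06), IFIT1, which binds viral RNA, by 4.88 ± 0.97 and the keratin gene KRT17 by 4.51 ± 0.98, and CMPK2 held 59 counts against 2 in DMSO (ratio 29.8, 95% counting interval 7.89 to 252). CTGF stood at −4.78 ± 1.05, −4.61 ± 1.01 and −4.21 ± 1.01 with RBN-2397 at 10 nM and RBN012337 at 3 and 10 nM. TIPARP rose by 1.36 ± 0.34 with RBN012337 at 10 nM (adjusted p = 0.0233) and stood at 0.81 to 1.25 at the other doses (adjusted p = 0.0645 to 0.142).

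The counts at these doses were 941 (547 higher, 394 lower) and 277 (216 higher, 61 lower) with RBN-2397 at 10 and 30 nM. With RBN012337 they were 1091 (637 higher, 454 lower) at 3 nM, 344 (239 higher, 105 lower) at 10 nM and 25 (25 higher) at 100 nM. Without DMSO replicate 1 they were 112 and 17 with RBN-2397 at 10 and 30 nM and 127 and 26 with RBN012337 at 3 and 10 nM; without DMSO replicate 3 they were 1505, 762, 1653 and 917. With RBN012337 at 100 nM the count ran from 1 (without DMSO replicate 2) to 68 (without treated replicate 2). With the replicate number as a block it was 795 with RBN-2397 at 30 nM, and 1851 and 38 with RBN012337 at 3 and 100 nM.

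In NCI-H647 the early response to RBN-2397 at 300 nM for 6 h held 1 called gene. FAM167A (ENSG00000154319.14, chromosome 8, 11421463 to 11475908) rose by 1.95 ± 0.33 (adjusted p = 0.00723), from 12.2 ± 6.46 to 50.9 ± 10.9 CPM (SD, n = 3). As lists, 14 TGF-beta and YAP targets were called higher (median 0.51, 12 of 14 positive, adjusted p = 0.000427, and adjusted p = 0.204 with an estimated correlation), with 1 member past the threshold adjusted over the list alone. The YAP partner gene AMOTL2 stood at 1.04 ± 0.27 (adjusted p = 0.149). The 21 ERK output and immediate early genes were called higher (median 0.61, adjusted p = 0.000427, and adjusted p = 0.338 with an estimated correlation), with 4 members adjusted over the list alone. The cyclin gene CCND1 stood at 0.79 ± 0.21 (adjusted p = 0.16) and the phosphatase gene DUSP5 at 1.21 ± 0.40 (adjusted p = 0.224). The other 21 tested lists were not called (adjusted p = 0.0912 to 0.873), among them the interferon-stimulated genes (median 0.29, adjusted p = 0.177) and the aryl hydrocarbon receptor targets (median 0.37, adjusted p = 0.177). CYP1B1 stood at 0.76 ± 0.62 (adjusted p = 0.655) and TIPARP at −0.15 ± 0.66 (adjusted p = 0.962).

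By edgeR 1827 genes had an unadjusted p under 0.05 in this comparison, and DESeq2 called 113. Without 1 library the edgeR count was 519 (DMSO replicate 1), 67 (treated replicate 3) or 0 (treated replicate 1, DMSO replicate 2 or DMSO replicate 3). At the other doses FAM167A alone was called, rising by 1.95 ± 0.33 with RBN-2397 at 10 nM (adjusted p = 0.0067). The edgeR count was 0 with RBN-2397 at 30 nM and with RBN012337 at 3, 10 and 100 nM, where 635, 769, 475 and 364 genes had an unadjusted p under 0.05 and DESeq2 called 1, 4, 4 and 0. For RBN-2397 at 10 nM these numbers were 1093 and 5. Without 1 library these counts reached 153, 2, 4 and 3 (DMSO replicate 1 left out; RBN-2397 at 10 and 30 nM, RBN012337 at 3 and 10 nM) and 1 (RBN012337 at 100 nM without its replicate 2), and with RBN012337 at 100 nM the blocked count was 1. Lists were called at each dose in NCI-H647 at 6 h (4 and 6 with RBN-2397 at 10 and 30 nM, and 5, 6 and 6 with RBN012337), and 1 held with an estimated correlation. This was the NF-kB list with RBN012337 at 10 nM, with a median of 1.10 and 12 of 19 members higher adjusted over the list alone (adjusted p = 2.71e-17, and adjusted p = 0.00568 with an estimated correlation). TIPARP ran from −0.08 to 0.92 (adjusted p = 0.994 to 1).

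After 24 h with RBN-2397 at 300 nM in NCI-H647, 33 of 51 interferon-stimulated genes rose and 0 fell (47 adjusted over the list alone), and all 51 had positive log2 changes (n = 3 per group). ISG15, a ubiquitin-like modifier, rose by 4.17 ± 0.81 (adjusted p = 0.00479), OASL by 3.86 ± 0.74, IFIT1 by 5.13 ± 1.06, MX1, a GTPase that blocks viral replication, by 5.51 ± 1.25 and OAS2 by 5.41 ± 1.16. The list median was 2.14 (adjusted p = 2.97e-35, and adjusted p = 0.121 with an estimated correlation). Of 19 NF-kB targets 5 rose (9 adjusted over the list alone), the chemokine genes CCL20 (3.30 ± 0.67), CXCL8 (1.74 ± 0.41) and CXCL1 (2.07 ± 0.54) and the cytokine gene IL1B (4.49 ± 0.99) among them (list adjusted p = 2.88e-05, and adjusted p = 0.13 with an estimated correlation). Of 15 PARP family genes 3 rose (6 adjusted over the list alone), PARP9 by 3.02 ± 0.71, PARP10 by 2.61 ± 0.68 and PARP12 by 2.10 ± 0.54 (list adjusted p = 0.00162, and adjusted p = 0.121 with an estimated correlation). Of 14 nucleic acid sensing genes 4 rose (6 adjusted over the list alone), including AIM2 (2.92 ± 0.69) and the RNA editing gene ADAR (1.05 ± 0.29). As a list they were called higher (adjusted p = 0.00682, and adjusted p = 0.213 with an estimated correlation). Of 17 MHC class I presentation genes PSMB8 rose by 1.21 ± 0.28 (list adjusted p = 0.00271, and adjusted p = 0.213 with an estimated correlation). Of 10 immune checkpoint ligands 2 rose (3 adjusted over the list alone), IDO1, an enzyme of tryptophan catabolism, by 5.10 ± 0.93 and NECTIN2 by 1.05 ± 0.21 (list adjusted p = 0.00642, and adjusted p = 0.128 with an estimated correlation).

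Further lists were called at 24 h in NCI-H647. Of 14 mesenchymal genes 2 rose (5 adjusted over the list alone), fibronectin FN1 by 2.12 ± 0.33 and the receptor kinase gene AXL by 1.21 ± 0.29 (list adjusted p = 1.05e-06, and adjusted p = 0.0904 with an estimated correlation). Of 14 TGF-beta and YAP targets 6 rose (6 adjusted over the list alone), including TGFBI (1.17 ± 0.20), with a list adjusted p = 0.00273 (adjusted p = 0.13 with an estimated correlation). Of 27 DNA replication genes 2 rose (8 adjusted over the list alone), MCM4 by 1.05 ± 0.29 and MCM5 by 1.15 ± 0.33, with a list adjusted p = 3.29e-09 (adjusted p = 0.213 with an estimated correlation). All 25 mitosis genes had positive log2 changes and 0 passed the threshold in edgeR (median 0.61, adjusted p = 2.31e-07, and adjusted p = 0.213 with an estimated correlation). Of 20 stress response genes 4 fell (8 adjusted over the list alone), ASNS at −4.70 ± 0.96, DDIT3 at −2.17 ± 0.47, SESN2 at −2.98 ± 0.72 and TRIB3 at −2.07 ± 0.60 (list adjusted p = 0.0135, and adjusted p = 0.213 with an estimated correlation). ASNS spread widely in DMSO here too (69.3, 100 and 7.64 CPM). The DMSO libraries moved with the replication and stress lists here too. Their replication scores of 3.79 to 5.56 (SD 0.89) lay on both sides of the 5.37 to 5.52 with RBN-2397 at 300 nM. Their stress response score was 6.03 ± 0.76 against 5.40 ± 0.04 (SD, n = 3). Of 20 p53 targets 2 fell, SESN2 and the repair gene XPC (−0.79 ± 0.22), with a list adjusted p = 0.0228 (adjusted p = 0.213 with an estimated correlation). The squamous differentiation list was called with 1 of 5 members higher, KRT17 by 3.66 ± 0.49 (adjusted p = 0.0113, and adjusted p = 0.185 with an estimated correlation).

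Of 9 epithelial adhesion and keratin genes KRT7 rose by 2.48 ± 0.67 (list adjusted p = 0.0233, and adjusted p = 0.265 with an estimated correlation). The markers of fibroblasts and endothelium, fixed as signs of other cells, were called higher with 0 of 6 members past the threshold and 2 adjusted over the list alone (adjusted p = 0.0339, and adjusted p = 0.128 with an estimated correlation). The endothelial adhesion gene PECAM1 stood at 1.55 ± 0.48 (adjusted p = 0.0614). The 34 ribosomal protein genes were called higher with a median of 0.18 (adjusted p = 0.00294, and adjusted p = 0.563 with an estimated correlation). Not called were glycolysis and hypoxia (2 higher of 18, adjusted p = 0.0511), aryl hydrocarbon receptor targets (0 of 12, adjusted p = 0.101), cholesterol synthesis (1 higher, 1 lower of 18, adjusted p = 0.358) and mitochondrially encoded transcripts (0 of 13, adjusted p = 0.412). Nor were ERK output (1 higher, 1 lower of 21, adjusted p = 0.412), apoptosis regulators (1 higher of 18, adjusted p = 0.785) and NRF2 targets (1 lower of 17, adjusted p = 0.785). The direction of NRF2 targets differed between the test (higher) and the median (−0.03). The lists of interferons and T-cell chemokines and of leukocyte markers had fewer than 5 tested members in each line, as had lung lineage in NCI-H647 and fibroblast and endothelial markers in NCI-H1373, and were not tested there. Among their members CXCL10 rose by 4.88 ± 1.27 in NCI-H647 and CCL5 (ENSG00000271503.5, chromosome 17, 35871491 to 35880793), which attracts T cells, by 2.09 ± 0.44 in NCI-H647 and 3.40 ± 0.63 in NCI-H1373. CD68, a macrophage marker, stood at 0.11 ± 0.32 and 0.39 ± 0.49 (adjusted p = 0.908 and 0.685). The lung lineage gene HOPX stood at 0.11 ± 0.61 in NCI-H647 (adjusted p = 0.956) and the collagen gene COL1A1 at −1.47 ± 0.63 in NCI-H1373 (adjusted p = 0.122). TIPARP stood at −0.04 ± 0.68 (adjusted p = 0.986) and CYP1B1, followed here after its response in NCI-H1373 was seen, at 0.97 ± 0.63 (adjusted p = 0.439).

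Across all genes 500 of 14789 were called, 328 higher and 172 lower. Among the 10 largest rises were MX1, OAS2, IFIT1, IDO1, the chemokine gene CXCL10 (4.88 ± 1.27), the growth factor gene CSF3 (4.97 ± 0.83) and the interferon-induced IFI27 (4.79 ± 1.01), while CXCL12 held 49 counts against 1 (ratio 40.1, 95% counting interval 6.86 to 1610). Among the 10 largest falls were ASNS, SESN2 and the replication-dependent histone gene HIST1H2BC (−3.20 ± 0.63), while WASH2P (−3.37 ± 0.88) and CCDC144B (−2.66 ± 0.74) are uncertain as members of families of near-identical copies. Without 1 library the count was 1390 (DMSO replicate 1), 118 and 143 (DMSO replicates 2 and 3), or 285, 249 and 114 (treated replicates 1, 2 and 3).

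At the other doses for 24 h in NCI-H647 the interferon-stimulated genes had 10 and 12 of 51 members called higher with RBN-2397 at 10 and 30 nM and 0 with RBN012337 at 3, 10 and 100 nM by edgeR. Adjusted over the list alone these counts were 44, 46, 25, 6 and 40, with medians of 1.82, 1.94, 1.38, 1.05 and 1.66. The list was called at each dose (largest adjusted p = 2.46e-15) and at none with an estimated correlation (adjusted p = 0.0958 to 0.296 with an estimated correlation). Replicate 2 of RBN012337 at 100 nM scored 3.56 over this list, within the DMSO libraries at 3.39 to 3.93, while replicates 1 and 3 scored 5.43 and 6.70. ASNS stood at −4.61 ± 0.97 with RBN-2397 at 30 nM and at −4.80 ± 0.96 and −4.46 ± 0.96 with RBN012337 at 3 and 10 nM. With RBN012337 at 100 nM KRT17 rose by 2.73 ± 0.49, the prostaglandin synthase gene PTGS2 by 3.07 ± 0.59 and RASD1 by 2.50 ± 0.45. CSF3 rose by 3.91 ± 0.84 with RBN012337 at 3 nM, and MX1 by 5.04 ± 1.23 and 5.23 ± 1.24 with RBN-2397 at 10 and 30 nM. TIPARP ran from −0.07 to 1.11 (adjusted p = 0.876 to 0.991).

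The counts were 266 (160 higher, 106 lower) and 139 (103 higher, 36 lower) with RBN-2397 at 10 and 30 nM. With RBN012337 they were 100 (54 higher, 46 lower), 26 (20 higher, 6 lower) and 15 (15 higher) at 3, 10 and 100 nM. Without DMSO replicate 1 the counts were 1194, 972, 922 and 221 with RBN-2397 at 10 and 30 nM and RBN012337 at 3 and 10 nM. The lowest were 29 (without DMSO replicate 2), 13 (without replicate 3), 4 (without replicate 2) and 0 (without replicate 3) in that order, and with RBN012337 at 100 nM the count ran from 4 (without replicate 3) to 212 (without replicate 2).

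Whether the compounds differ was asked at the shared dose of 10 nM and at the top doses of 300 nM for RBN-2397 and 100 nM for RBN012337, which differ. At 10 nM edgeR called 0 genes at 6 and 24 h in NCI-H1373 and at 6 and 24 h in NCI-H647 (153, 250, 363 and 456 with an unadjusted p under 0.05; 0, 1, 2 and 2 by DESeq2). At 6 h in NCI-H1373 the count was 1 with the replicate number as a block, and 1 without replicate 3 of RBN012337. The interferon list score with RBN-2397 minus RBN012337 at 10 nM was −0.05 (95% interval −0.82 to 0.72) at 6 h and −0.04 (−0.81 to 0.73) at 24 h in NCI-H1373, and −0.08 (−1.17 to 1.0) and 0.84 (−0.24 to 1.92) in NCI-H647. This last interval was 0.13 to 1.55 with the replicate number as a block, and the others still held 0. The score of aryl hydrocarbon receptor targets differed by −0.32 (−0.99 to 0.34) at 6 h in NCI-H1373. TIPARP differed by −0.43 (−1.06 to 0.21) and −0.37 (−1.02 to 0.28) in NCI-H1373 at 6 and 24 h. As lists, NF-kB targets were lower with RBN-2397 at 6 h in NCI-H647 (median −0.54, adjusted p = 1.96e-06, and adjusted p = 0.356 with an estimated correlation). Interferon-stimulated genes were higher at 24 h in NCI-H647 (median 0.81, adjusted p = 1.82e-14, and adjusted p = 0.322 with an estimated correlation). Also called higher there were MHC class I presentation, nucleic acid sensing, immune checkpoint ligands, mitosis, epithelial adhesion and keratins and mesenchymal genes, and each call was lost (adjusted p = 0.0945 to 0.322 with an estimated correlation). At 24 h in NCI-H1373 lung lineage was called higher (median 0.77, adjusted p = 0.0313, and adjusted p = 0.469 with an estimated correlation).

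At the top doses 17 genes differed at 24 h in NCI-H1373, 10 higher with RBN-2397 and 7 higher with RBN012337. The transcription factor gene HOXA3 was higher with RBN-2397 by 2.42 ± 0.47, the ERK phosphatase gene DUSP5 stood at −2.51 ± 0.54 and the ubiquitin ligase gene RNF11 at −1.47 ± 0.29. PTP4A3, a phosphatase gene with no count in RBN012337 libraries, was at least 8.33-fold higher. Of 27 DNA replication genes 8 were higher with RBN-2397 adjusted over the list alone (list adjusted p = 1.16e-07, and adjusted p = 0.344 with an estimated correlation), and the list scores differed by 0.69 (95% interval 0.25 to 1.12). Without replicate 2 of RBN012337 this was 0.40 (−0.04 to 0.85). The interferon list score differed by 0.89 (0.12 to 1.66, and 0.10 to 1.67 with the replicate number as a block) in NCI-H1373 at 24 h. Same-numbered libraries differed by 0.62, 2.11 and −0.08, and without replicate 2 of RBN012337 the value was 0.34 (−0.42 to 1.09). In NCI-H647 at 24 h it differed by 0.91 (−0.18 to 1.99, and 0.20 to 1.62 with the block), and by 0.07 (−0.95 to 1.09) without replicate 2 of RBN012337. Within RBN012337 at 100 nM in NCI-H1373 this score was 5.43, 4.55 and 6.97 in replicates 1, 2 and 3. The count of 17 was 1344 without replicate 3 of RBN012337, 2 without replicate 1 of RBN-2397 and 0 without any other of the 6 libraries, and 650 with the replicate number as a block.

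At 6 h in NCI-H1373 edgeR called 0 genes between the top doses (1468 with an unadjusted p under 0.05, and 82 by DESeq2), 362 with the block, 457 without replicate 3 of RBN012337 and 15 without replicate 3 of RBN-2397. In NCI-H647 it called 0 at 6 and at 24 h (1224 and 748 with an unadjusted p under 0.05, 1 and 5 by DESeq2). The number of lists called at the top doses was 2 and 6 at 6 and 24 h in NCI-H1373 and 0 and 7 in NCI-H647, and 0 held with an estimated correlation. Log2 changes from DMSO at the top doses correlated across genes, which are not independent replicates, with r = 0.443 and 0.631 at 6 and 24 h in NCI-H1373 and 0.497 and 0.682 in NCI-H647. Unchanged groups that share DMSO gave r = 0.511, 0.513, 0.516 and 0.534 in simulation. All 25 genes called with RBN012337 at 100 nM in NCI-H1373 at 24 h were also called higher with RBN-2397 at 300 nM, as were all 15 in NCI-H647. Independent calls would share 1.71 and 0.333 genes, not counting the shared DMSO libraries.

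Dose was read from list scores of the top minus the lowest dose of each compound. The interferon score differed by 0.59 (95% interval −0.18 to 1.36) with RBN-2397 at 24 h in NCI-H1373. Same-numbered libraries differed by −0.15, 1.15 and 0.77. The DNA replication score was lower with RBN012337 at 100 than at 3 nM at 24 h in NCI-H1373, by −0.87 (−1.31 to −0.43). In NCI-H647 the mean difference of −0.64 (−1.27 to −0.02) rests on replicate 2, since same-numbered libraries differed by −0.05, −1.82 and −0.06. The plot of replication scores shows that the spread between libraries was wide in these 100 nM groups and in DMSO.

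**Figure D4:**
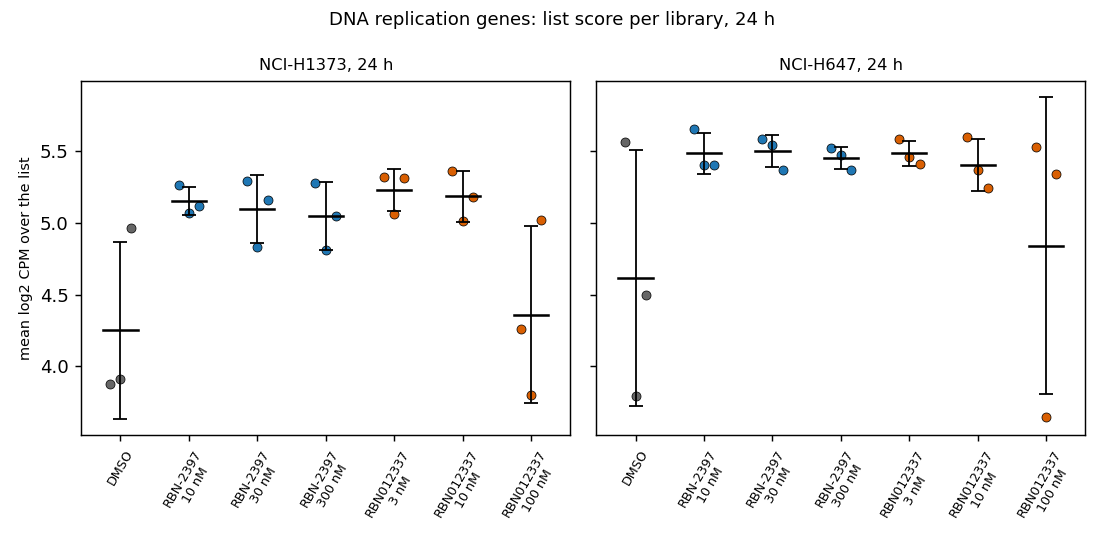
Mean log2 CPM over 27 DNA replication genes (y axis) per library at 24 h for DMSO and each compound and dose (x axis), by line; points are the 3 libraries, lines the mean and bars the SD. The SD is 0.611 to 1.036 in DMSO and RBN012337 at 100 nM and 0.075 to 0.239 in the other 10 groups.

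Whether the response to RBN-2397 at 300 nM changed between times was tested as a difference of log2 changes. In NCI-H1373 47 genes differed, 27 with a larger value at 24 h and 20 with a larger value at 6 h. The interferon-induced genes IFITM1 (5.09 ± 1.18) and IFI27 (3.30 ± 0.77) were higher at 24 h, and the transcription factor genes MAFK (−3.63 ± 0.81) and NFATC2 were higher at 6 h. NFATC2 held 34 counts against 2 in DMSO at 6 h (ratio 13.3, 95% counting interval 3.42 to 114), so the size of its difference is poorly set. Of 51 interferon-stimulated genes 3 had a larger response at 24 h (39 adjusted over the list alone), with a median difference of 1.87 (adjusted p = 1.11e-33, and adjusted p = 0.0696 with an estimated correlation). In NCI-H647 the same list had a median difference of 1.89 with 16 members adjusted over the list alone (adjusted p = 5.64e-31, and adjusted p = 0.224 with an estimated correlation), and edgeR called 0 genes (829 with an unadjusted p under 0.05, and 6 by DESeq2). The responses at both times correlated across genes with r = 0.321 in NCI-H1373 and 0.323 in NCI-H647.

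The NCI-H1373 count of 47 between times was 0 without any of 7 libraries, namely replicate 1 or 2 of the 6 h treatment, DMSO replicate 1 or 2 of 6 h, DMSO replicate 2 of 24 h, and replicate 2 or 3 of the 24 h treatment. It was 14 and 390 without DMSO replicates 1 and 3 of 24 h, 18 without replicate 3 of the 6 h treatment and 111 without DMSO replicate 3 of 6 h. In NCI-H647 it was 2 without DMSO replicate 1 of 24 h.

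Whether the lines differ in their response to RBN-2397 at 300 nM was tested over all 84 libraries and 16177 genes. At 24 h 30 genes differed, 18 with a larger value in NCI-H1373 and 12 with a larger value in NCI-H647. The stress cytokine gene GDF15 (4.95 ± 1.13) and IGFBP6 (2.96 ± 0.68) were higher in NCI-H1373, and the collagen gene COL4A1 (−5.59 ± 1.24), the protease inhibitor gene TFPI2 (−3.88 ± 0.69) and the phosphatase gene DUSP1 (−3.18 ± 0.71) were higher in NCI-H647. The response of the mitosis list was lower in NCI-H1373 (median −0.72, 0 of 25 members past the threshold, adjusted p = 3.08e-13, and adjusted p = 0.282 with an estimated correlation). The response of TGF-beta and YAP targets was lower as well, with 1 of 14 past the threshold and 4 adjusted over the list alone (adjusted p = 0.000246, and adjusted p = 0.0822 with an estimated correlation). Responses at 24 h correlated across 12240 genes with r = 0.497, and 125 genes rose and 78 fell in both lines (16.5 and 8.58 by chance), with 0 in opposite directions.

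At 6 h edgeR called 0 genes between the lines (729 with an unadjusted p under 0.05, and 9 by DESeq2; 1 without replicate 3 of the NCI-H1373 treatment). At 24 h the count of 30 moved over 1.5 times without each of the 12 libraries. It was 90 (DMSO replicate 3), 13 and 10 (DMSO replicates 1 and 2) and 18, 10 and 15 (treated replicates 1, 2 and 3) in NCI-H1373. In NCI-H647 it was 61, 58 and 18 (DMSO replicates 1, 2 and 3) and 13, 8 and 13 (treated replicates 1, 2 and 3).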

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

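The tests of explanations for the 3 patterns weighed at the end of this part were all chosen after the patterns were seen, while the differences between times and lines and the splits of the libraries were planned. The number of regroupings for the lines was raised to 40 after smaller numbers had been counted, because the share at 24 h turned on where the draws stopped.

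The response of NCI-H1373 to RBN-2397 at 300 nM differed between the 2 times by a direct test of the difference, which called 47 genes. The log2 response at 24 h exceeded that at 6 h by 11.04 for LGALS9, 7.0 for LINC00881, 5.35 for RIBC2, 5.09 for IFITM1 and 3.30 for IFI27. It was lower at 24 h for NFATC2 (−6.51), MAFK (−3.63), MB21D2 (−3.15), FRMD6 (−3.10) and C3orf52 (−2.94). LGALS9, LINC00881 and RIBC2 held 0 or 1 count in the 24 h DMSO libraries, so their fitted values are no bounds, and LGALS9 is uncertain because of near-identical copies. NFATC2 held 2 counts in the 6 h DMSO libraries, so its value is poorly set too. Lists also differed, with larger medians at 24 h for interferon-stimulated genes (1.87), lung lineage (0.96), glycolysis and hypoxia (0.88), DNA replication (0.60), ribosomal proteins (0.58), nucleic acid sensing (0.51), PARP family (0.50), MHC class I presentation (0.49) and mitochondrially encoded transcripts (0.45). Medians were smaller at 24 h for TGF-beta and YAP targets (−0.94) and ERK output (−0.88). With an estimated correlation none of these 11 lists passed (adjusted p = 0.0696 to 0.261).

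In NCI-H647 the difference between times was seen in lists alone, since edgeR called 0 genes. Medians were larger at 24 h for interferon-stimulated genes (1.89), mitosis (0.75), nucleic acid sensing (0.55), DNA replication (0.50), NF-kB targets (0.48), MHC class I presentation (0.44), PARP family (0.40) and mesenchymal genes (0.39). They were smaller for ERK output (−0.56) and the unfolded protein and integrated stress response (−0.24). None of these 10 lists passed with an estimated correlation (adjusted p = 0.204 to 0.370) or with fry (adjusted p = 0.0628 to 0.397).

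Between the lines the response at 24 h differed in 30 genes by a direct test. The log2 response in NCI-H1373 exceeded that in NCI-H647 by 11.70 for HRASLS2, 6.43 for CGNL1, 4.95 for GDF15, 3.07 for ATP9A and 2.96 for IGFBP6. It was lower for COL4A1 (−5.59), SPANXC (−5.34), SDCBP2 (−5.01), TFPI2 (−3.88) and DUSP1 (−3.18). HRASLS2, CGNL1, COL4A1 and SPANXC passed the count filter in 1 of the lines alone, so their fitted differences are no bounds, and SPANXC is uncertain because of near-identical copies. SDCBP2 held 3 counts in the treated NCI-H1373 libraries against 75 in DMSO (ratio 29.7, 95% counting interval 9.78 to 147), so its value is poorly set. The lists of mitosis (median −0.72), TGF-beta and YAP targets (−0.52) and glycolysis and hypoxia (0.41) differed at 24 h, and those of mitochondrially encoded transcripts (−0.42) and ribosomal proteins (−0.26) at 6 h. With an estimated correlation these 5 lists did not pass (adjusted p = 0.0822 to 0.865).

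These differences were compared with regroupings that exchange treated and DMSO libraries within a time or line, ignore the replicate number and include the real grouping. For the difference between times 5 of 40 regroupings in NCI-H1373 called as many genes as the real one (47, against 1747 in the highest other), and in NCI-H647 all 40 did (0, against 1420). For the difference between lines all 40 regroupings at 6 h called as many (0, against 1167) and 8 of 40 at 24 h (30, against 1775). Where the real count is 0 every regrouping is level by construction, so these 2 comparisons say nothing on chance. The highest regroupings kept the treatment of 24 h, or of NCI-H1373, whole. At 6 h, or in NCI-H647, they set DMSO replicates 2 and 3 with treated replicate 3. By construction 6 regroupings in each comparison, these among them, hold the whole response of 1 time or line, so they are no picture of chance. Of the 33 others that keep none whole, 1 called as many for the times in NCI-H1373 (857) and 5 for the lines at 24 h (178 in the highest), so chance is not excluded by these counts. They bear on the fit without the replicate number alone, since with it as a block 396 and 146 genes were called and no regroupings were drawn.

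Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. For RBN-2397 at 10, 30 and 300 nM at 6 h in NCI-H1373 the real split called 40, 3 and 206 genes against at most 1, 325 and 3 in another, so 1, 3 and 1 splits called as many. For RBN012337 at 3, 10 and 100 nM it called 60, 25 and 0 against 1, 0 and 4, with 1, 1 and 10 splits as high. At 24 h in NCI-H1373 the values were 941, 277 and 1525 against 46, 835 and 52 for RBN-2397 (1, 2 and 1 splits) and 1091, 344 and 25 against 1, 50 and 203 for RBN012337 (1, 1 and 5 splits). In NCI-H647 at 6 h they were 1, 0 and 1 against 0, 1 and 91 for RBN-2397 (1, 10 and 4 splits) and 0, 0 and 0 against 0, 1 and 220 for RBN012337 (10 splits each). At 24 h in NCI-H647 they were 266, 139 and 500 against 161, 1 and 1 for RBN-2397 (1 split each) and 100, 26 and 15 against 0, 6 and 1792 for RBN012337 (1, 1 and 5 splits).

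Between the compounds at 10 nM the real split and the highest other called 0 in each of the 4 comparisons, so all 10 splits were level. At the top doses the real split called 0, 17, 0 and 0 genes (6 and 24 h in NCI-H1373, then in NCI-H647) against 0, 270, 1 and 0 in the highest other, with 10, 2, 10 and 10 splits as high.

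In 7 comparisons another split called several times the real number, which points to a structure of the libraries across treatment. In NCI-H1373 the highest split for RBN-2397 at 30 nM at 6 h, and for RBN-2397 at 30 nM and RBN012337 at 100 nM at 24 h, set DMSO replicate 3 and treated replicates 1 and 3 against the rest. In NCI-H647 it set DMSO replicate 1 with treated replicates 1 and 3 (RBN012337 at 100 nM, both times) or 1 and 2 (RBN-2397 at 300 nM, 6 h). For the top doses at 24 h in NCI-H1373 it set replicate 1 of RBN-2397 and replicates 1 and 2 of RBN012337 against the rest. Replicate numbers pair the libraries in 16 comparisons, where the real split parts 3 same-numbered pairs. In these the 3 other splits that part 3 pairs called at most 1 gene, and the high counts came from the 6 splits that part 1 pair and keep 2 pairs whole. With the replicate number as a block the counts of the paired comparisons among the 7 were 16 (RBN-2397 at 30 nM, 6 h), 795 and 38 (RBN-2397 at 30 nM and RBN012337 at 100 nM, 24 h) and 650 (top doses, 24 h) in NCI-H1373, and 1 (RBN012337 at 100 nM, 6 h) in NCI-H647.

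The first pattern is that fewer genes were called with rising dose of RBN012337 at 24 h in NCI-H1373 (1091, 344 and 25). Lower depth of the 100 nM libraries would leave the size of the changes in place, but over the 1484 genes called with RBN-2397 at 300 nM outside the interferon list the median change toward that response was 0.10 at 100 nM (0.10, 0.09 and 1.04 per library) against at least 0.98 in each library at 3 nM. An exchange with DMSO is not decided by the interferon list for replicate 2. Its 4.55 exceeded the highest DMSO score (4.32) by less than the DMSO SD (0.365). Replicates 1 and 3 scored higher. Stronger inhibition near the IC90 as a general cause is argued against by RBN-2397, whose 300 nM libraries moved by a median of 1.17 over the 1070 genes called with RBN012337 at 3 nM outside the interferon list, against 1.15 at 10 nM. What set replicates 1 and 2 at 100 nM apart stays open. A state shared with DMSO (next pattern) would also give low values, since the genes were chosen against DMSO.

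The second pattern is a wide spread of the DNA replication score at 24 h in DMSO and RBN012337 at 100 nM of both lines (SD 0.611 to 1.036) against 0.075 to 0.239 in the other 10 groups. Counting noise of shallow libraries is argued against at equal depth (counts thinned to the lowest total of the line, mean of 20 draws), where the 4 groups kept an SD of at least 0.574 against at most 0.231 in the other 10. Growth that was still faster at 24 h without an effective dose is argued against by the score itself. It was lower in the 4 groups than at the other 5 doses in both lines (−0.835 and −0.736), whichever 1 of their libraries was left out (−0.438 nearest to 0). Faster growth earlier in the exposure is not decided, since a score at 24 h does not record it. A condition shared by the DMSO and 100 nM cultures of a replicate, such as plate position, may contribute: same-numbered libraries differed by 0.26 on average against 0.75 over all pairings, and 2 of 36 pairings were as close (exact one-sided p = 0.0556). It cannot be told apart from chance or from a biological difference between cultures, because the labels give no plate and the pairings are few. The stress response score was also uneven in these 4 groups (SD 0.44 to 0.764, against 0.011 to 0.361 in the other 10).

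The third pattern is replicate 1 of RBN-2397 at 300 nM at 6 h in NCI-H1373, at the DMSO level of CYP1B1. Too few counts are argued against, since 53 were found where 1610 were expected from replicates 2 and 3. An exchange with a DMSO library of 6 h is argued against by the highest of these at 18.3 CPM, below the lowest of the other 17 treated libraries at 112 CPM. A well that received no compound, or a wrong label, may explain the level of 11.2 CPM, but other values lean against it. Over 100 genes ranked without it, this library lay 0.39 to 1.03 toward the treated side of the DMSO libraries left out, which lay 0.06 to 0.80 apart. By multidimensional scaling it lay at −0.66 and −0.62, near replicate 1 at 10 nM (−0.43 and −0.76) and away from DMSO replicate 1 (−1.13 and 0.01). It cannot be told apart from a culture that responded in part, since the DMSO libraries lie almost as far apart and the labels hold nothing on single wells. No biological explanation was tested for this library.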

How the results depend on the processing

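Alternatives chosen after the data were seen are named above, and the others were planned. All counts are edgeR calls unless DESeq2 is named. They are given for RBN-2397 at 10, 30 and 300 nM and then RBN012337 at 3, 10 and 100 nM, and counts within 1.5 times the reported one are left out. Except where stated, the cause was not tested.

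RLE scaling and the stricter filter left all 36 counts within 1.5 times. The 289 calls of named genes kept their direction under every alternative, and they also kept their side of the threshold in 289 with RLE, 288 with the replicate block, 278 of 289 with no filter, 258 of 259 with the stricter filter, 249 of 289 with DESeq2 and 191 of 192 with the depth covariate. They kept it in 166 of 227 without 3 DMSO libraries, 106 of 226 with the groups of the contrast alone, 47 of 187 in 1 depth set and 981 of 1851 values with 1 library left out. Fewer libraries are the construction of these last 4.

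DESeq2 called 181, 29, 327, 196, 52 and 2 genes at 6 h in NCI-H1373, and at 24 h 450 (RBN-2397 at 30 nM) and 65 (RBN012337 at 100 nM). In NCI-H647 it called 5, 1, 113, 4 and 4 at 6 h (all but RBN012337 at 100 nM) and 519, 353, 767, 338, 75 and 56 at 24 h. Between compounds at 10 nM it called 1 at 24 h in NCI-H1373 and 2 and 2 at 6 and 24 h in NCI-H647, and at the top doses 82 and 180 in NCI-H1373 and 1 and 5 in NCI-H647. Between times it called 208 and 6 in NCI-H1373 and NCI-H647, and between lines 9 and 89 at 6 and 24 h.

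With no filter the counts were 407, 142, 511, 441, 184 and 48 at 6 h in NCI-H1373, and at 24 h 581 (RBN-2397 at 30 nM), 575 and 177 (RBN012337 at 10 and 100 nM). In NCI-H647 they were 127, 96, 235, 85, 84 and 64 at 6 h and 786, 629, 905, 609, 281 and 295 at 24 h. Between compounds at 10 nM they were 40 and 41 in NCI-H1373 and 56 and 70 in NCI-H647 at 6 and 24 h, and at the top doses 401, 374, 80 and 72 in the same order. Between times they were 308 and 166, and between lines 62 and 189.

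With the replicate number as a block they were 505, 16, 830, 547 and 66 at 6 h in NCI-H1373 (all but RBN012337 at 100 nM), and at 24 h 1667 and 795 (RBN-2397 at 10 and 30 nM), 1851, 897 and 38 (RBN012337). In NCI-H647 they were 4, 2, 5, 2, 1 and 1 at 6 h and 764, 488, 1064, 457, 85 and 85 at 24 h. Between compounds the block gave 1 at 10 nM at 6 h in NCI-H1373, 362 and 650 at the top doses in NCI-H1373 at 6 and 24 h, and 1 at 24 h in NCI-H647. Between times it gave 396 in NCI-H1373, and between lines 11 and 146. It changed no other count by over 1.5 times, and the 61 list calls of RBN-2397 at 300 nM and RBN012337 at 100 nM against DMSO all held with it.

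With the groups of the contrast alone, a fit with fewer libraries, the counts at 6 h in NCI-H1373 were 1 and 60 (RBN-2397 at 30 and 300 nM) and 3 (RBN012337 at 100 nM), and at 24 h 149, 6, 455, 325, 50 and 0. In NCI-H647 they were 0, 1, 2 and 3 at 6 h (RBN-2397 and RBN012337 at 3 nM) and 61, 54, 72, 6, 8 and 1 at 24 h. Between compounds they were 1 at 10 nM in NCI-H1373 at 24 h and in NCI-H647 at 6 and 24 h, and at the top doses 3 in NCI-H1373 at 24 h and 1 and 1 in NCI-H647. Between times the count was 1 in NCI-H647, and between lines 1 at 24 h.

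In NCI-H1373 the depth covariate gave 272, 7, 470, 301 and 52 at 6 h (all but RBN012337 at 100 nM), and at 24 h 577 (RBN-2397 at 30 nM), 1651 and 626 (RBN012337 at 3 and 10 nM), with 158 and 234 at the top doses and 173 between times. In 1 depth set alone, with fewer libraries, the count was 0 (RBN-2397 at 30 nM) and 15 (RBN012337 at 10 nM) at 6 h and 0, 1, 228, 4, 2 and 1 at 24 h. It was 1 between compounds at 10 nM at 6 h, 206 and 1 at the top doses and 14 between times. Without the 3 DMSO libraries the count in NCI-H1373 was that without replicate 3 of 24 h, given above. In NCI-H647 it was then 0 and 0 at 6 h (RBN-2397 at 10 and 300 nM) and 93, 35, 176, 21, 14 and 4 at 24 h. With RBN012337 at 100 nM in place of RBN-2397 the differences between times in NCI-H1373 and between lines at 24 h were 0 and 0.

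With 1 library left out at a time the counts at 6 h in NCI-H1373 ran from 0 to 191, 0 to 163, 0 to 358, 0 to 257, 2 to 20 and 0 to 1, and at 24 h from 112 to 1505, 17 to 762, 470 to 1900, 127 to 1653, 26 to 917 and 1 to 68. In NCI-H647 they ran from 0 to 153, 0 to 2, 0 to 519, 0 to 4, 0 to 3 and 0 to 1 at 6 h, and from 29 to 1194, 13 to 972, 114 to 1390, 4 to 922, 0 to 221 and 4 to 212 at 24 h. Between compounds in NCI-H1373 they ran from 0 to 1 at 10 nM at 6 h. They ran from 0 to 457 and 0 to 1344 at the top doses there, and the others stayed at 0. Between times they ran from 0 to 390 and 0 to 2, and between lines from 0 to 1 and 8 to 90.

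For RBN-2397 at 300 nM the number of lists called fell to 0 with an estimated correlation in each of the 4 comparisons (from 6 and 10 in NCI-H1373 at 6 and 24 h, and 2 and 16 in NCI-H647). For RBN012337 at 100 nM it fell to 1 and 5 in NCI-H1373 (from 3 and 11) and to 0 and 0 in NCI-H647 (from 6 and 7). With fry it was 0 and 5 for RBN012337 at 100 nM in NCI-H1373, 0 and 0 in NCI-H647, and 1 for RBN-2397 at 300 nM at 6 h in NCI-H647. Of the 61 list calls in these 8 comparisons 6 held with an estimated correlation and 31 with fry. Over genes called in either comparison the correlation between compounds at the top doses was 0.723 and 0.853 in NCI-H1373 and 0.946 in NCI-H647 at 24 h (too few genes at 6 h). It was 0.491 and 0.717 between times and 0.811 and 0.707 between lines at 6 and 24 h; such a set is chosen for change, which raises the correlation by construction. The block leaves score differences in place by construction, and it moved the interval off 0 for the interferon score between compounds at 24 h in NCI-H647 (0.84 at 10 nM and 0.907 at the top doses). With 1 library left out the interferon score between compounds at 10 nM ran from −0.165 to 0.006 and −0.327 to 0.177 in NCI-H1373 at 6 and 24 h and from −0.273 to 0.094 and 0.427 to 1.272 in NCI-H647. At the top doses at 24 h it ran from 0.336 to 1.546 and 0.07 to 1.642 in the 2 lines.

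TIPARP, not called in NCI-H647 or between times, changed its sign in 45 repeats (adjusted p = 0.629 to 1). At 6 h in NCI-H647 this happened without 3 DMSO libraries for RBN-2397 at 10 nM (from −0.08 to 0.68) and 300 nM (from −0.15 to 0.62), and with DESeq2 for RBN012337 at 3 nM (from 0.05 to −0.10). At 24 h it happened without 3 DMSO libraries for RBN-2397 at 30 and 300 nM (from −0.065 to 0.025 and from −0.043 to 0.042) and RBN012337 at 3 nM (from −0.061 to 0.029). With no filter the value at 300 nM was 0.007. Between times in NCI-H1373 it moved from 0.008 to −0.017 (no filter), −0.003 (stricter filter), −0.007 (block) and −0.002 (depth covariate). In NCI-H647 it moved from 0.10 to −0.57 (without 3 DMSO libraries).

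With 1 library left out TIPARP at 6 h in NCI-H647 ran from −0.44 to 0.68, −0.14 to 1.04 and −1.27 to 0.61 for RBN-2397, and from −0.30 to 0.82 for RBN012337 at 3 nM. DMSO replicate 2 gave the highest value in all 4. At 24 h it ran from −0.082 to 0.26, −0.21 to 0.14 and −0.20 to 0.17 for RBN-2397, and from −0.32 to 0.19 for RBN012337 at 3 nM. Between times it ran from −0.63 to 0.39 in NCI-H1373 and from −0.63 to 1.25 in NCI-H647. DMSO replicate 2 of 6 h gave the lowest value in both lines.

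Depth, spread and the 3 libraries of a group together limit what could be called, and the simulation did not vary them apart. On simulated data 14.3% of 2-fold changes were recovered at 24 h in NCI-H1373 and 10.0% in NCI-H647. Low counts of called genes thus do not show that few genes responded.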

Other observations

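The values in this part were looked up after the results were seen, and no explanation was tested for them. Of the replication-dependent histone genes tested at 24 h with RBN-2397 at 300 nM, 0 of 22 were called higher and 2 lower in NCI-H1373 (median log2 change −0.15), and 0 of 29 were called higher and 4 lower in NCI-H647 (7 adjusted over these genes alone, median −0.03). CTGF, among the largest falls at 24 h, was at 96.6, 91.6 and 8.68 CPM in DMSO replicates 1, 2 and 3 of NCI-H1373.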
